A study of Mus musculus with 12 samples.

How the data were processed

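Small RNAs bound to AGO2 were measured in mouse embryonic stem cells that carried a doxycycline-inducible AGO2 with HA and FLAG tags. Per the labels' protocols, doxycycline at 2.5 ug/ml was added 15 h before harvest, cells were fractionated, AGO2 was immunoprecipitated with the anti-FLAG M2 antibody, and RNA was ligated to a barcoded 3' adapter and a 5' adapter, reverse transcribed and amplified by PCR. The 12 libraries formed 4 groups of 3, given by fraction (nuclear or total) and by doxycycline (added or not). The labels call the other fraction "Total", while the protocol and the design text speak of a cytoplasmic fraction. The name total fraction is kept here, and whether it included the nuclei was not settled.

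The deposited table held estimated counts (the unit the authors name is expected counts), which the authors made from aligned reads and averaged over each group, for 689 miRNA entries under older miRBase names, 119 of them marked with a star for the less abundant strand of a hairpin and 149 with a -3p or -5p suffix. It gave 1 column per group, so each value is the authors' mean and no per-library value was used here. That each value is a mean over 3 libraries was inferred from the values. Multiplied by 300, 100% of the values in each column were whole to within 0.0001, and multiplied by 3, between 78.4% and 91.4% were whole to within 1e-06. Per the submitters' processing notes, bcl2fastq 2.17.1, TopHat and the mm10 build were used; the counting step and the treatment of reads that match several miRNAs are not given in the sources used here. Values that are not whole after multiplication by 3 point to reads divided between entries, so members of families with near-identical copies, such as miR-467a and miR-467b, are uncertain individually.

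The planned tests (the quasi-likelihood test of edgeR, and DESeq2, limma-voom, camera and fry as alternatives) need per-library counts and were not run. In their place, the log2 fold was computed from mean counts scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, over entries with a mean count of at least 10 in at least 1 of the compared columns. Each fold has a 95% Clopper-Pearson interval for the ratio of the reads over the group, which are the mean counts times 3, rounded to whole reads for the interval. For the difference between the doxycycline folds of both fractions (the interaction), a normal approximation to counting error was used. Reads came from PCR without molecular identifiers, so intervals and floors cover counting error only. An entry at 0 was set to a floor of 3 reads over the group and its fold is given as a bound. A fold of at least 2 was used to count entries, as a rule of size and not a test. Shares of reads have 95% Wilson intervals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

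The groups, the lists and the rule for named miRNAs were set before the data were examined. The 16 lists covered the miR-290-295, miR-302 and miR-367, miR-17-92 (with its paralogous clusters), Dlk1-Dio3, Sfmbt2 and miR-183, miR-96 and miR-182 clusters, the let-7, miR-200, miR-15/16, miR-29 and miR-30 families, Drosha-independent miRNAs, and markers of fibroblast and mesenchymal, neural, blood, and muscle and liver cells. Any arm of a listed miRNA counted as a member. For lists with at least 3 tested members, the median log2 fold was placed among 10000 random lists of the same size, each member replaced by 1 of its 40 nearest neighbours in abundance. Such percentiles describe these columns and are not a test across replicates. The rule named, per comparison, the 8 most abundant entries, up to 8 with the largest rise and 8 with the largest fall among tested entries above the median abundance (the mean log2 level over the compared groups), the 2 most abundant members of each list, and miR-29b with miR-29a and miR-29c. The rule's conditions on an adjusted p and on groups that do not overlap were replaced by the 2-fold size and a counting interval that excludes no change, because the table holds no replicates. That replacement, the 2-fold size and the counts of lists outside the middle 95% were set after the table was seen.

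Hairpins were located with RefSeq symbols and GENCODE vM21 on GRCm38, the same assembly as mm10. A RefSeq miRNA gene was matched to 656 of the 689 entries and 33 had none. GC content was taken over the hairpin.

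The procedure was tested on simulated counts with Poisson error only and with the library totals of each comparison. Entries made 2-fold different were recovered, with the right sign and a counting interval that excluded no change, in 94.7% of cases between the fractions with doxycycline (363 entries), 79.1% for nuclear doxycycline against none (533 entries), 64.8% for total doxycycline against none (455 entries) and 86.0% between the fractions without doxycycline (196 entries). For 4-fold differences these shares were 100%, 97.8%, 86.2% and 100%. Unchanged entries reached 2-fold in 0%, 11.0%, 14.6% and 0% of cases, and the intervals held the true value in 95.0% to 97.0%. The TMM step was not part of that simulation.

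The alternatives were median-of-ratios factors, library totals, no filter and a minimum of 10 CPM (counts scaled to a common total) in at least 1 column. Added after seeing the data were mean counts without scaling, removal of miR-805, and subtraction of the counts without doxycycline from those with it, both as they stand and multiplied by the ratio of miR-805 with over without doxycycline. The planned pseudocounts applied to normalized values only and were not needed.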

Results

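Mouse embryonic stem cells, grown on gelatin with the cytokine LIF, carried a copy of AGO2 with HA and FLAG tags that doxycycline switches on. AGO2 is the Argonaute protein that holds a miRNA and pairs it with target RNA. Small RNAs that came down with the anti-FLAG antibody were sequenced from the nuclear and from the total fraction, with and without doxycycline, in 3 libraries per group and 12 in all. Cells without doxycycline served as the control for RNA that binds without the induced protein. The authors gave 1 mean count per miRNA and group, so there was no replicate check for any difference, and errors are 95% counting intervals.

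The authors' mean for the sum of all miRNA counts was 400794 reads per library in the nuclear and 539627 in the total fraction with doxycycline. Without doxycycline it was 36329.9 and 16053.4 reads. A count of 0 therefore allowed up to 2.50 and 1.85 CPM (reads scaled to a common total) with doxycycline, but 27.5 and 62.3 CPM without it. Of 689 entries, 363 had a mean count of at least 10 in the nuclear and 357 in the total fraction with doxycycline, against 175 and 139 without it.

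The sum of miRNA reads with doxycycline was 11.0 times (10.96 to 11.10) that without it in the nuclear fraction and 33.6 times (33.3 to 33.9) in the total fraction. Such ratios also depend on how deeply each library was sequenced, which cannot be told apart from induction here. Without miR-805, which alone took 63.7% of nuclear and 33.3% of total reads in cells without doxycycline, these ratios were 29.4 (29.1 to 29.7) and 49.9 (49.4 to 50.5). The miR-290-295 cluster, the main miRNA cluster of mouse embryonic stem cells, took 65.7% (Wilson interval 65.6 to 65.8) of nuclear and 68.8% (68.7 to 68.9) of total reads with doxycycline. Its share without doxycycline was 14.3% (14.1 to 14.5) and 32.1% (31.7 to 32.6), or 39.3% and 48.2% without miR-805. miR-17-92 and its paralogous clusters, which promote proliferation, took 8.18% and 7.99% with doxycycline and 1.97% and 4.19% without it; without miR-805 these were 8.46%, 8.06%, 5.43% and 6.28%. The let-7 family, which accumulates as cells differentiate, took 0.129% and 0.160% with doxycycline and 0.343% and 1.21% without it, the latter 0.945% and 1.81% without miR-805. The imprinted Dlk1-Dio3 cluster took 4.62% and 5.12% with doxycycline and 3.00% and 3.31% without it. With miR-805 left out the direction of the Dlk1-Dio3 share turned in the nuclear fraction, to 4.78% with and 8.25% without doxycycline, where miR-337-3p alone had 379 of the cluster's 1088.5 mean reads. The total fraction had 5.16% and 4.95% with overlapping intervals (5.13 to 5.19 and 4.72 to 5.20).

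Nuclear and total AGO2 with doxycycline were compared to ask whether AGO2 in the nucleus holds the same miRNAs as AGO2 in the total fraction. If the total fraction held whole cells, it included nuclear AGO2, which would make differences smaller and ranks more alike. The cluster members that dominated both fractions differed little: miR-294 had a log2 fold (nuclear over total) of -0.27 (-0.28 to -0.26), miR-291a-3p 0.27 (0.26 to 0.28, but -0.14 without scaling), miR-293 -0.26 and miR-295 -0.31. All 14 arms of the cluster lay within 2-fold. Among entries above the median abundance, the miRNAs furthest above the total fraction were miR-1949 at 2.73 (2.46 to 3.00), miR-193 at 2.19 (1.97 to 2.42), miR-805 at 1.96 (1.93 to 1.99) and miR-136* at 1.64 (1.48 to 1.79). Furthest below, among the same entries, were miR-30e* at -1.42 (-1.57 to -1.27), miR-669d at -1.29 (-1.43 to -1.15), miR-18b, a miR-17-92 paralogue, at -1.15 (-1.33 to -0.99) and let-7g at -1.02 (-1.23 to -0.81).

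The nuclear reads behind these folds differed in their background. miR-1949 had 233.7 mean nuclear reads with doxycycline and 282.7 without it, and miR-805 had 13121 and 23133.7. By contrast miR-15a, known to restrain the cell cycle, had 1349.3 and 23.3 at a log2 fold of 1.41 (1.34 to 1.49), and miR-136 had 1173 and 39 at 1.41. miR-297c of the Sfmbt2 cluster reached 1.14 with 534.6 and 5.91 reads, and miR-32 reached 1.11 (0.95 to 1.27) with 266.3 and 4.33. The values of miR-297c point to reads divided between entries, and miR-297a was at 0.60. On GRCm38 miR-294 lies between genes at chr 7 3220641-3220724, miR-1949 in an exon of Gm28285 at chr 18 35554567-35554636, and miR-136 in the Dlk1-Dio3 region at chr 12 109595327-109595388. miR-15a lies in an intron of Dleu2 at chr 14 61632027-61632110, miR-297c in an intron of Sfmbt2 at chr 2 10509016-10509113 and miR-32 in an intron of Tmem245 at chr 4 56895229-56895298. miR-30e lies in an intron of Nfyc at chr 4 120772606-120772697, let-7g in an intron of Wdr82 at chr 9 106178840-106178927 and miR-18b at chr X 52742331-52742413. miR-193 and miR-669d matched several copies, and miR-805 had no RefSeq miRNA gene.

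**Figure D1:**
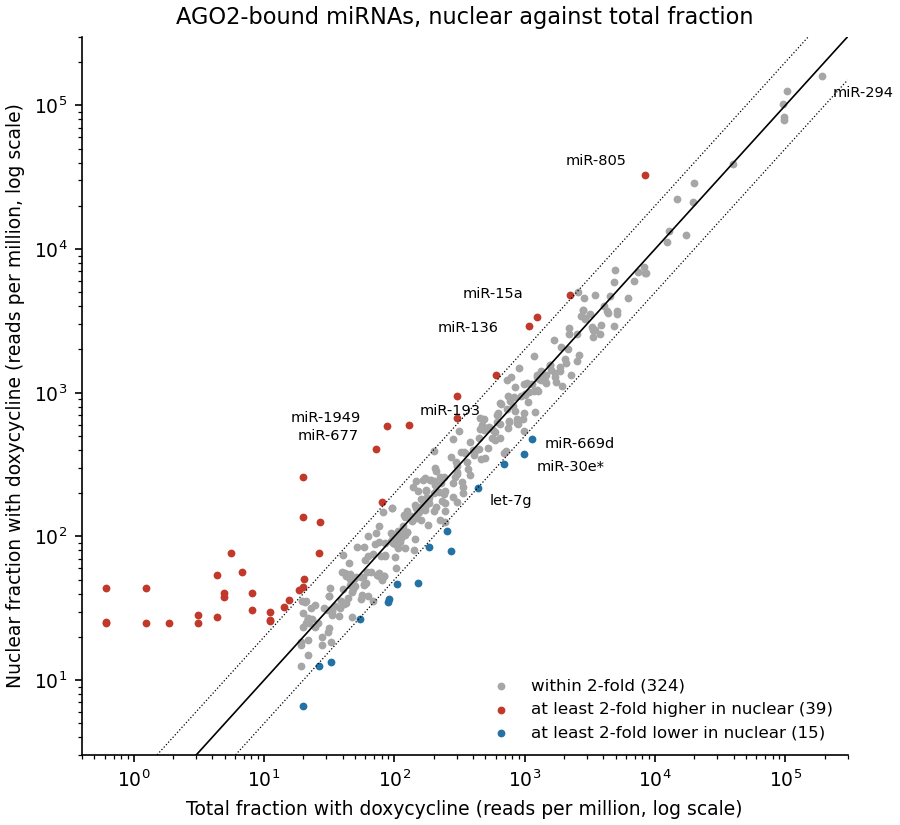
CPM of each tested miRNA in the total fraction (horizontal, log axis) and the nuclear fraction (vertical, log axis), both with doxycycline; each point is the authors' mean of 1 entry, red at least 2-fold higher and blue at least 2-fold lower in the nuclear fraction after TMM scaling. The solid line marks equal CPM, dotted lines mark 2-fold in CPM, and most of the 378 entries lie between them.

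Of 10 arms of the miR-30 family, 4 were at least 2-fold lower in the nuclear fraction and 0 higher, and all 4 were star strands, among them miR-30c-1* at -1.69 and miR-30e* at -1.42. Its unstarred arms were not lower, with miR-30a at 0.01 (-0.10 to 0.12), miR-30e at 0.05 (-0.00 to 0.10) and miR-30c at 0.70 (0.60 to 0.80). The family median of -0.41 (percentile 1.74 of abundance-matched lists) lay between the star and the unstarred arms. It turned to 0.14 with the reads without doxycycline subtracted, when miR-30b* no longer had a fold, while miR-30c-1* went to -2.81 and miR-30e* to -1.81. Of 8 let-7 arms, 1 was lower, let-7g, which came within 2-fold at -0.80 with the reads without doxycycline subtracted, and 7 lay within 2-fold (median -0.20, percentile 12.5). Of 21 arms of miR-17-92 and its paralogues, 1 was higher and 2 lower (median -0.23, percentile 6.34), with miR-19b at 0.57 (0.55 to 0.60) and miR-106b at -0.16 (-0.19 to -0.12). The Dlk1-Dio3 cluster had 3 higher, 0 lower and 64 within 2-fold (median -0.11, percentile 16.8), with miR-127 at -0.33 (-0.37 to -0.30) and miR-379 at -0.75 (-0.80 to -0.69). The Sfmbt2 cluster, a large cluster of repeated hairpins, had 3 higher, 1 lower and 30 within (median -0.02 but mean 0.03, percentile 74.6; median 0.02 with median-of-ratios factors).

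The cluster of miR-302 and miR-367, like miR-290-295 a stem cell cluster, had all 6 arms within 2-fold (median 0.06, percentile 70.8; -0.35 without scaling). The median of the miR-290-295 cluster was -0.01 (percentile 60.1; 0.01 by library totals). Medians were -0.10 (percentile 38.8; 0.26 with the reads without doxycycline subtracted) for the 9 arms of the miR-200 family, which maintains epithelial state, and -0.18 (29.1) for the 4 arms of miR-183, miR-96 and miR-182, all within 2-fold. The miR-15/16 family had 1 of 10 arms higher (median 0.03, percentile 69.5; -0.38 without scaling). In the miR-29 family, which targets collagens and DNA methyltransferases, all 3 arms lay within 2-fold (median 0.02, percentile 64.5; -0.39 without scaling), with miR-29b at 0.78 (0.61 to 0.95), miR-29a at -0.06 (-0.17 to 0.05) and miR-29c at 0.02 (-0.34 to 0.37). The 3 Drosha-independent miRNAs lay within 2-fold (median 0.17, percentile 77.1; -0.25 without scaling). Among markers of other cells, the fibroblast and mesenchymal list had 1 of 7 lower (median -0.30, percentile 4.27) and the neural list 1 higher and 1 lower of 8 (median -0.08, percentile 42.4). Of 6 blood cell arms, 2 were higher (median 0.17, percentile 72.2; -0.24 without scaling), and both tested muscle and liver markers lay within 2-fold (median 0.12).

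**Figure D2:**
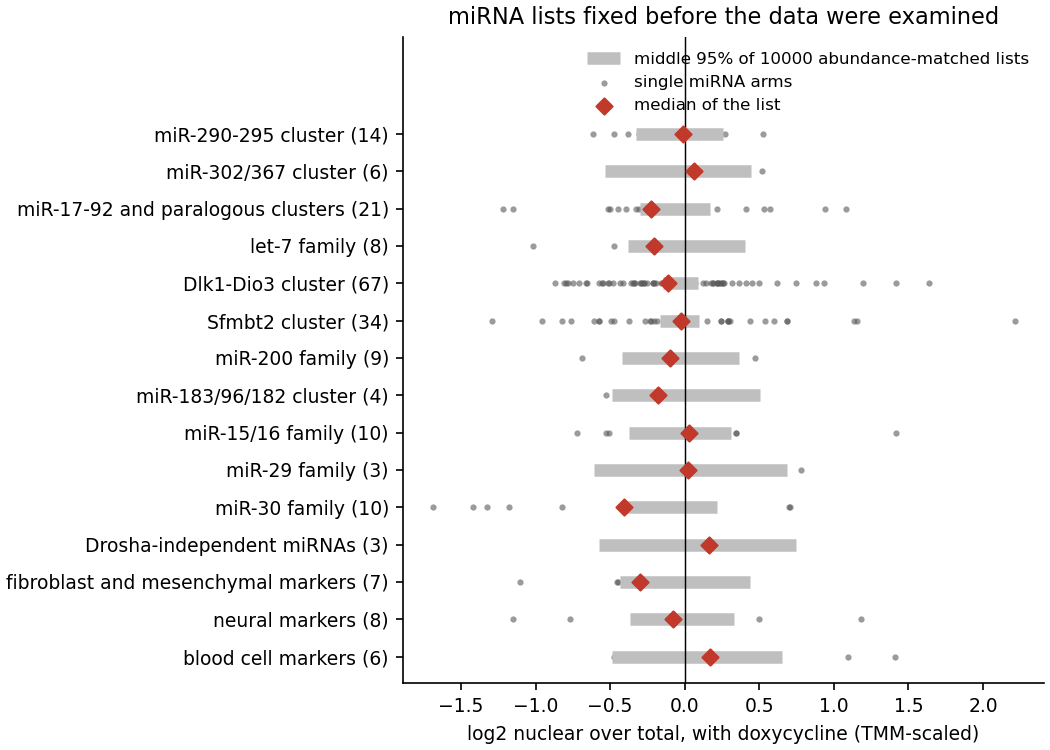
Log2 fold of nuclear over total mean counts with doxycycline (horizontal axis, TMM-scaled) for the arms of each list; points are single arms, diamonds list medians, grey bars the middle 95% of matched random lists, and numbers in brackets the arms tested. The miR-30 family median of -0.41 lies below its bar, between star strands under it and unstarred arms above it, and turned to 0.14 with the reads without doxycycline subtracted, when miR-30b* lost its fold.

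Of 378 tested entries, 39 were at least 2-fold higher and 15 at least 2-fold lower in the nuclear fraction, and counting intervals of all of them excluded no change. Many of the 39, such as miR-1192 (10.2 nuclear and 0.33 total mean reads) and miR-682 (10 and 0.33), reached the minimum of 10 only in the nuclear fraction. The direction of such a fold followed from the filter. Some of the 15 reached it only in the total fraction, such as miR-26b* (2.67 and 10.7). Levels ranked alike in both fractions (Spearman's rho 0.96 across miRNAs, which are not independent replicates). Without scaling the counts were 28 higher and 44 lower, with a median log2 fold of -0.46 against -0.04. With the reads without doxycycline subtracted they were 15 and 31, and with the scaled subtraction 20 and 17.

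In the nuclear fraction, cells with and without doxycycline were compared to ask which miRNAs depended on the induced AGO2. Relative to the typical miRNA, and among entries above the median abundance, the gains were largest for miR-363 at a log2 fold of 3.97 (2.75 to 5.60), miR-106a at 3.96 (3.32 to 4.74), miR-106b at 3.43 (3.12 to 3.77), miR-130a at 3.41 (3.12 to 3.72) and miR-93 at 3.38 (3.00 to 3.83). All of these but miR-130a belong to miR-17-92 paralogous clusters. miR-294 gained 2.52 (2.46 to 2.58), from 718.8 to 64361 mean reads, and miR-291a-3p 2.56 (2.49 to 2.63). The liver miRNA miR-122 was lowest at -6.44 (-6.73 to -6.16), with 41.2 mean reads against 227.7 without doxycycline. miR-878-3p at -5.81 (-6.24 to -5.39), miR-124* at -5.66 (-5.99 to -5.33), miR-21* at -5.26 (-5.53 to -5.00) and miR-337-3p at -5.24 (-5.40 to -5.09) also had fewer reads with doxycycline. miR-805 was at -4.79 (-4.80 to -4.77).

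Of the lists, miR-17-92 and its paralogues had 11 arms at least 2-fold higher and 6 lower of 21 (median 1.68, percentile 99.5). All 6 lower arms were star strands. The Dlk1-Dio3 cluster had 30 higher and 14 lower of 64 (median 0.90, percentile 100), with miR-127 at 2.34 (2.06 to 2.64), and the Sfmbt2 cluster 15 higher and 3 lower of 33 (median 0.93, percentile 99.98), with miR-467a at 2.30 (1.75 to 2.98). The miR-290-295 cluster had 7 higher and 4 lower of 14 (median 1.05, percentile 65.5). The muscle and liver list, 3 arms, had the lowest median (-6.10, percentile 0), with 2 lower, miR-122 and miR-1. Its other arm, miR-499, was at 0.44 (0.01 to 0.88), so the list did not fall as a whole. miR-1 had 11.7 mean reads without doxycycline, close to the minimum for testing. Where only cells without doxycycline reach that minimum, a low fold follows from the filter. The percentile therefore cannot show a fall across the list. The let-7 family had 0 higher and 4 lower of 7 (median -1.47, percentile 21.5), but 2.49 without scaling. Median and mean differed in sign for the miR-200 family (0.31 and -1.22), the miR-15/16 family (1.28 and -0.12) and the miR-29 family (0.19 and -1.10). The 3 lower arms of the miR-200 family and the 1 lower arm of the miR-29 family were star strands.

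Of 371 tested entries, 113 were at least 2-fold higher and 125 lower in these relative terms, against 151 and 107 by library totals and 301 and 15 without scaling. The median log2 fold over all entries was 0.04, 0.55 and 4.01 in that order. In reads, 330 entries had more with doxycycline and 41 fewer, 229 had at least 10 times more, and 84 of the 125 lower ones had more. On these 371 entries rho across miRNAs was 0.44.

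Among entries above the median abundance, the same comparison in the total fraction gave the largest relative gains for miR-106a at 4.67 (3.78 to 5.97), for miR-431 at 3.96 (2.92 to 5.28) and miR-543 at 3.63 (2.27 to 5.51) of the Dlk1-Dio3 cluster, and for miR-18a at 3.51 (2.87 to 4.25). miR-294 gained 2.56 (2.49 to 2.63), from 544.1 to 103485 mean reads. Lowest of these entries were miR-200c* at -6.62 (-7.17 to -6.09), miR-193* at -5.67 (-6.10 to -5.25), miR-1949 at -5.60 (-5.92 to -5.28) and miR-677 at -5.41 (-5.77 to -5.06). miR-122 was at -5.34 (-5.64 to -5.05), with 59 mean reads against 74.3, and miR-805 at -5.26 (-5.29 to -5.22). miR-29c had no read without doxycycline and a log2 fold of at least 0.39, the lower limit of its counting interval.

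miR-17-92 and its paralogues had 10 arms at least 2-fold higher and 5 lower of 21 (median 0.81, percentile 98.2), and all 5 lower arms were star strands. The Dlk1-Dio3 cluster had 29 higher and 14 lower of 66 (median 0.70, percentile 99.9). The Sfmbt2 cluster had 14 higher and 6 lower of 34 (median 0.10, percentile 64.0). The let-7 family had 0 higher and 6 lower of 8 (median -2.02, percentile 4.15), but a median of 2.99 without scaling. The miR-30 family had 2 higher and 5 lower of 10 (median -1.73, percentile 4.66), but 3.28 without scaling; all 5 lower arms were star strands, and its unstarred arms ranged from miR-30e at -0.31 to miR-30d at 1.14. Median and mean differed in sign for the miR-290-295 cluster (0.64 and -0.03, with 6 higher and 4 lower of 14) and the neural markers (0.15 and -0.25).

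**Figure D3:**
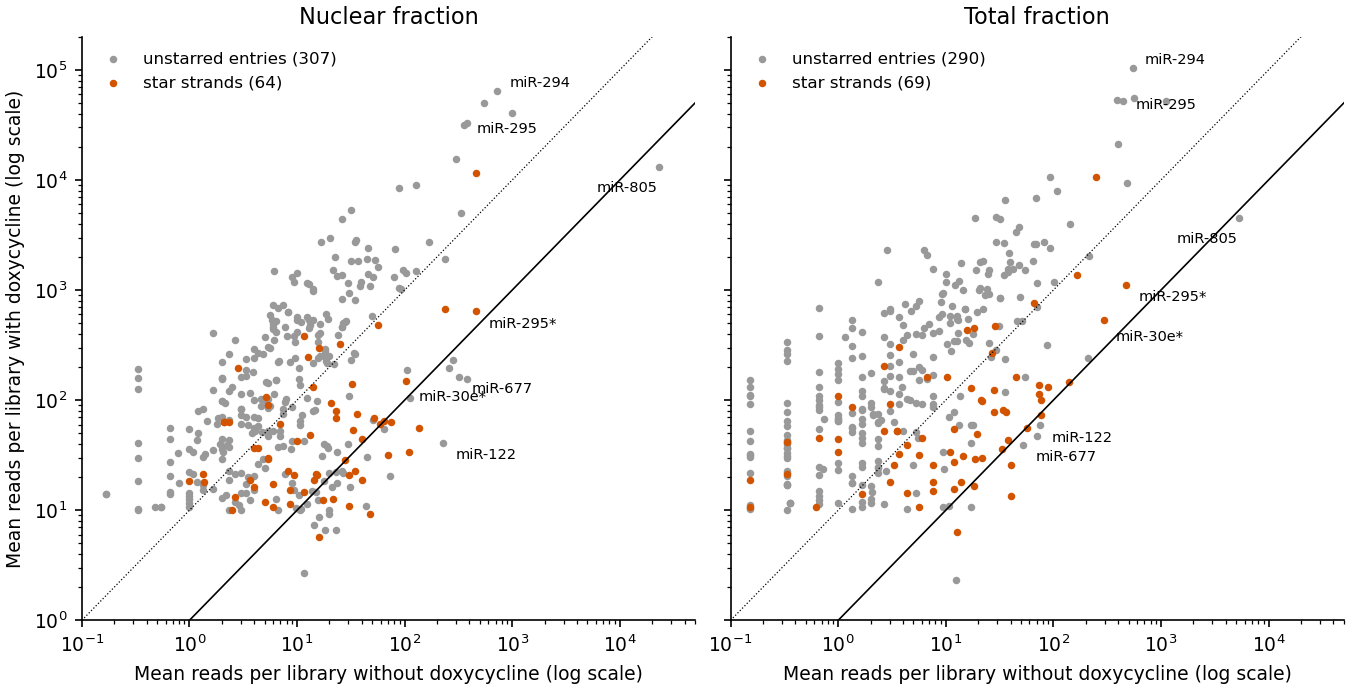
The authors' mean reads per miRNA without doxycycline (horizontal, log axis) and with it (vertical, log axis), in the nuclear and the total fraction; orange points are star strands, the solid line marks equal reads, the dotted line 10 times more with doxycycline, and entries with 0 reads without doxycycline are drawn at 0.15. In the nuclear fraction 41 and in the total fraction 12 of the tested entries had fewer reads with doxycycline.

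Of 359 tested entries, 114 were at least 2-fold higher and 115 lower in relative terms, against 330 and 2 without scaling, where the median log2 fold was 5.05 instead of 0.04. In reads, 347 entries had more with doxycycline and 12 fewer, 273 had at least 10 times more, and 103 of the 115 lower ones had more. Over 345 entries tested in both fractions, 78 were higher in both, where independent lists would share 37.3, and 81 were lower in both, against 29.6. Levels in the fractions were not independent, with rho 0.96 across miRNAs with doxycycline and 0.67 without it. Sharing above those values is therefore no separate check.

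Without doxycycline the fractions were compared to describe the reads present without induction. Their source, the antibody or otherwise, was not tested. Without miR-805, the miR-290-295 cluster took 39.3% of them in the nuclear and 48.2% in the total fraction. Of the entries above the median abundance, miR-337-3p was furthest above the total fraction at a log2 fold of 4.37 (3.92 to 4.85), with 379 nuclear and 13.7 total mean reads, followed by miR-714 at 3.15 (2.59 to 3.76), miR-878-3p at 2.34 (1.80 to 2.93) and miR-677 at 2.20 (1.96 to 2.46). miR-805 was at 1.69 (1.66 to 1.71) and miR-1949 at 1.57 (1.36 to 1.80). Of the same entries, miR-30e* was lowest at -1.93 (-2.13 to -1.75), before miR-320, which is made without Drosha, at -1.82 (-2.21 to -1.45) and miR-1965 at -1.72 (-1.93 to -1.51). miR-294 was at -0.02 (-0.12 to 0.07).

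The let-7 family had 3 of 4 arms at least 2-fold lower in the nuclear fraction (median -1.48, percentile 0.63), with let-7f at -1.71 (-2.25 to -1.19), and the miR-30 family 5 of 7 (median -1.23, percentile 1.11), of which 4 were star strands and the other was miR-30e at -1.23 (-1.52 to -0.95). The miR-290-295 cluster had 1 higher and 13 within 2-fold (median -0.47, percentile 25.3). The Dlk1-Dio3 cluster had 8 higher and 4 lower of 29 (median 0.05, percentile 60.1; -0.70 by library totals). Of 189 tested entries 45 were higher and 32 lower, against 29 and 76 by library totals and 59 and 15 without scaling, with medians over all entries of -0.09, -0.84 and 0.34. No arm of miR-302 or miR-367 had enough reads to be tested.

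The interaction, the nuclear minus the total log2 fold for doxycycline, asked whether induction acted differently on a miRNA in the fractions. It also takes in any difference between the fractions without doxycycline, where reads were few. Above the median abundance, it was highest for miR-193 at 2.96 (2.20 to 3.72), miR-434-5p of the Dlk1-Dio3 cluster at 2.88 (2.06 to 3.70), and miR-467a and miR-467b of the Sfmbt2 cluster, each at 2.57 (1.92 to 3.22). miR-15a followed at 1.98 (1.49 to 2.47) and miR-320 at 1.96 (1.58 to 2.35). Some of these rested mainly on the fractions without doxycycline. There miR-467a was at -2.38 (24 against 95 reads over the group) and miR-320 at -1.82, against -0.01 and -0.06 with doxycycline. miR-193 and miR-15a differed mainly with doxycycline, at 2.19 and 1.41, against -0.57 and -0.36 without it. Among entries above the median abundance, miR-337-3p, also of the Dlk1-Dio3 cluster, was lowest at -3.23 (-3.73 to -2.74). It came before miR-339-5p at -2.53 (-3.28 to -1.78) and miR-221 at -2.50 (-3.87 to -1.13). Between the fractions without doxycycline these 3 were at 4.37, 2.64 and 2.25. The interaction of miR-294 was -0.05 (-0.14 to 0.05).

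The miR-30 family had 5 of 10 arms at least 1 log2 unit higher and 0 lower (median 0.92, percentile 98.4), but a median of -0.12 without scaling; the 5 were its unstarred arms. Of 3 Drosha-independent miRNAs 2 were higher (median 1.79, percentile 98.8). The Dlk1-Dio3 cluster had 10 higher and 20 lower of 63 (median -0.08, mean -0.40, percentile 17.1). The let-7 family had 3 of 7 higher (median 0.76, percentile 96.3), but a median of -0.28 without scaling. Median and mean differed in sign for the cluster of miR-302 and miR-367 (-0.38 and 0.26; median 0.19 by library totals) and for the fibroblast and mesenchymal markers (0.08 and -0.05; median -0.96 without scaling). Of 345 entries 57 were higher and 56 lower, against 131 and 36 by library totals and 9 and 168 without scaling, with medians over all entries of 0.10, 0.67 and -0.94. The split of these counts changed with the scaling.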

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

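The rule on counting intervals and the unscaled values were chosen only after the table was seen. Among the named miRNAs, 4 had counting intervals for doxycycline against none on opposite sides of no change in the nuclear and the total fraction. With group means only, intervals took the place of single samples, and the difference was not tested against replicates. miR-193 had a log2 fold of 0.66 in the nuclear and -2.30 in the total fraction. miR-434-5p had 1.79 in the nuclear and -1.08 in the total fraction, where it came close to no change without the filter. miR-30e had 1.18 in the nuclear and -0.31 in the total fraction, where it was 0.69 without the filter and 4.70 without scaling. miR-499 had 0.44 in the nuclear and -0.48 in the total fraction, where it was 0.52 without the filter and 4.53 without scaling. In mean reads all of them had more with than without doxycycline in both fractions, so the opposite signs are relative to the typical miRNA. For miR-193 these were 239 against 9.67 nuclear and 69.7 against 10.7 total mean reads. The fractions also differed without doxycycline, at a log2 fold of -3.11 for miR-434-5p and -1.23 for miR-30e. With doxycycline miR-30e was at 0.05, so its opposite signs came mainly from the cells without doxycycline. By contrast miR-193 was at 2.19 with and -0.57 without it, and miR-499 at 0.34 and -0.38.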

How the results depend on the processing

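The unscaled counts, the removal of miR-805 and both subtractions were chosen after seeing the data. The statements on direction that rest on reads alone did not depend on scaling, while most counts in relative terms did. Numbers of reads do depend on how deeply each library was sequenced, so they cannot separate induction from depth. No paired analysis was possible because only group means are given. For the same reason the quasi-likelihood test, DESeq2, limma-voom, the set tests with preset and estimated correlation, fry, a replicate block, 1 fit over all 12 libraries, leave-one-out fits and permutation tests were planned and not run, and pseudocounts were planned for normalized values only. Median-of-ratios factors left all 20 main results in place and 311 of the other values within their counting interval or the tolerance for list medians, with 16 moved and 1 reversed. Removal of miR-805 left 22 main results and 323 others in place and moved 16 main results, all of them ratios of total reads or shares of reads. Library totals left 16 of the 20 in place, no filter 9, the CPM filter 11 and unscaled counts 12. Depth without doxycycline limits every fold against those cells: 175 nuclear and 139 total entries reached a mean of 10 reads. Of values that changed sign, only called ones are named below: folds whose counting interval excluded no change and list medians outside the middle 95%, both by the TMM value with the filter. Sign changes of uncalled values were counted instead. Among the named folds there were 8 with median-of-ratios factors, 15 by library totals, 19 without the filter, 18 with the CPM filter, 25 without scaling, 2 without miR-805 and 5 with each subtraction. Among the list medians there were 5, 7, 17, 14, 32, 0 and 3 in the same order. The TMM value with the filter stands in parentheses; the cause of each change was not tested, except that fewer filters test more entries by construction (602 against 378 between the fractions with doxycycline) that unscaled counts carry the difference in total reads, and that both subtractions leave miR-30b* without a fold, which shifts the miR-30 family median from between its star and unstarred arms to an unstarred arm.

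With median-of-ratios factors between the fractions with doxycycline, the called value that changed sign was miR-292-3p at 0.0055 (-0.04).

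By library totals, entries at least 2-fold apart were 29 higher (45) and 76 lower (32) between the fractions without doxycycline and 131 higher (57) and 36 lower (56) for the interaction. In the nuclear fraction, the called doxycycline fold that changed sign was miR-142-3p at 0.060 (-0.44). For the interaction, the called value that changed sign was miR-142-3p at 0.077 (-0.49).

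Without the filter, entries at least 2-fold apart were 152 higher (39) and 37 lower (15) between the fractions with doxycycline, 247 higher (113) and 245 lower (125) for doxycycline in the nuclear fraction, 188 higher (114) and 204 lower (115) for doxycycline in the total fraction, 160 higher (45) and 75 lower (32) between the fractions without doxycycline and 231 higher (57) for the interaction. There were 2 lists below the middle 95% (1) between the fractions with doxycycline and 1 list below the middle 95% (0) for doxycycline in the total fraction. Between the fractions with doxycycline, the called values that changed sign were miR-292-5p at -0.13 (0.08), miR-200a at -0.077 (0.13) and miR-497 at -0.039 (0.17). In the nuclear fraction, the called doxycycline folds that changed sign were let-7f at 0.31 (-1.50), miR-466c-5p at 0.83 (-0.98), miR-142-5p at 0.86 (-0.95) and miR-142-3p at 1.36 (-0.44). In the total fraction, the called doxycycline folds that changed sign were miR-291a-5p at 0.27 (-0.73), miR-92a at 0.80 (-0.20), miR-30e at 0.69 (-0.31) and miR-499 at 0.52 (-0.48). For the interaction, the called value that changed sign was miR-142-3p at 0.32 (-0.49).

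With the CPM filter, entries at least 2-fold apart were 86 higher (39) between the fractions with doxycycline, 243 higher (113) and 249 lower (125) for doxycycline in the nuclear fraction, 186 higher (114) for doxycycline in the total fraction, 160 higher (45) and 75 lower (32) between the fractions without doxycycline and 219 higher (57) for the interaction. There was 1 list above the middle 95% (0) between the fractions with doxycycline and 1 list below the middle 95% (0) for doxycycline in the total fraction. Between the fractions with doxycycline, the called value that changed sign was miR-292-5p at -0.018 (0.08). In the nuclear fraction, the called doxycycline folds that changed sign were let-7f at 0.28 (-1.50), miR-466c-5p at 0.79 (-0.98), miR-142-5p at 0.83 (-0.95) and miR-142-3p at 1.33 (-0.44). In the total fraction, the called doxycycline folds that changed sign were miR-291a-5p at 0.27 (-0.73), miR-92a at 0.80 (-0.20), miR-30e at 0.69 (-0.31) and miR-499 at 0.52 (-0.48). For the interaction, the called value that changed sign was miR-142-3p at 0.29 (-0.49).

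Without scaling, entries at least 2-fold apart were 44 lower (15) between the fractions with doxycycline, 301 higher (113) and 15 lower (125) for doxycycline in the nuclear fraction, 330 higher (114) and 2 lower (115) for doxycycline in the total fraction, 15 lower (32) between the fractions without doxycycline and 9 higher (57) and 168 lower (56) for the interaction. Between the fractions with doxycycline, the called values that changed sign were miR-291a-3p at -0.14 (0.27), miR-292-5p at -0.34 (0.08), miR-200a at -0.28 (0.13), miR-497 at -0.24 (0.17), miR-16 at -0.069 (0.34), miR-484 at -0.069 (0.34) and miR-499 at -0.071 (0.34). In the nuclear fraction, the called doxycycline folds that changed sign were let-7a at 1.84 (-2.13), let-7f at 2.47 (-1.50), miR-466c-5p at 2.99 (-0.98), miR-30e* at 0.55 (-3.42), miR-145 at 1.16 (-2.80), miR-142-5p at 3.02 (-0.95) and miR-142-3p at 3.52 (-0.44). In the total fraction, the called doxycycline folds that changed sign were miR-291a-5p at 4.28 (-0.73), miR-92a at 4.81 (-0.20), let-7a at 1.59 (-3.42), let-7g at 2.71 (-2.30), miR-30e at 4.70 (-0.31), miR-30e* at 0.87 (-4.13), miR-320 at 3.29 (-1.72), miR-145 at 1.72 (-3.29), miR-124* at 0.39 (-4.62), miR-142-5p at 3.57 (-1.44) and miR-499 at 4.53 (-0.48). Between the fractions without doxycycline, the called values that changed sign were miR-92a at 0.22 (-0.20) and miR-124 at 0.014 (-0.41). For the interaction, the called values that changed sign were miR-805 at -0.57 (0.47), miR-292-5p at -0.18 (0.87), miR-291a-3p at -0.090 (0.95), miR-293 at -0.62 (0.42), miR-295 at -0.39 (0.65), miR-292-3p at -0.038 (1.00), miR-293* at -0.77 (0.28), miR-19b at -0.094 (0.95), miR-92a at -0.77 (0.27), miR-141 at -0.35 (0.69), miR-96 at -0.18 (0.86), miR-29a at -0.44 (0.60), miR-30e* at -0.32 (0.72), miR-142-5p at -0.55 (0.50), miR-499 at -0.12 (0.92) and the miR-30 family median at -0.12 (0.92).

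With the reads without doxycycline subtracted, entries at least 2-fold apart were 15 higher (39) and 31 lower (15) between the fractions with doxycycline. There were 0 lists below the middle 95% (1) between the fractions with doxycycline. Between the fractions with doxycycline, the called values that changed sign were miR-292-3p at 0.093 (-0.04) and the miR-30 family median at 0.14 (-0.41).

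With the scaled subtraction, entries at least 2-fold apart were 20 higher (39) between the fractions with doxycycline. Between the fractions with doxycycline, the called values that changed sign were miR-292-3p at 0.048 (-0.04) and the miR-30 family median at 0.098 (-0.41).

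Without miR-805, reads with over without doxycycline were 29.4 (11.0) in the nuclear and 49.9 (33.6) in the total fraction, by construction of the smaller totals. The share of the miR-290-295 cluster became 67.9% (65.7%) in the nuclear and 69.4% (68.8%) in the total fraction with doxycycline, and 39.3% (14.3%) and 48.2% (32.1%) without it. Without the most abundant entry of each group, these shares were 59.1%, 61.4%, 39.3% and 48.2%. For miR-17-92 and its paralogues the share without miR-805 was 8.46% (8.18%) and 8.06% (7.99%) with doxycycline and 5.43% (1.97%) and 6.28% (4.19%) without it. Without the most abundant entry it was 9.75%, 9.89%, 5.43% and 6.28%. For the Dlk1-Dio3 cluster the share without miR-805 was 4.78% (4.62%) and 5.16% (5.12%) with doxycycline and 8.25% (3.00%) and 4.95% (3.31%) without it, so that the nuclear direction turned. Without the most abundant entry it was 5.51%, 6.33%, 8.25% and 4.95%. For the let-7 family the share without miR-805 was 0.945% (0.343%) and 1.81% (1.21%) in cells without doxycycline. Without the most abundant entry it was 0.154%, 0.199%, 0.945% and 1.81%. Those changes follow from the smaller totals.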

Other observations

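Of the tests below, the removal of miR-805, the entries without a gene, the abundance matching and the strand comparison of star strands, both subtractions with their low-background part, and the counting bound were chosen only after the result was seen. The arms of miR-142, a blood cell miRNA, lay apart: between the fractions with doxycycline miR-142-5p was at a log2 fold of 1.10 (1.04 to 1.16) and miR-142-3p at -0.47 (-0.53 to -0.42). Without doxycycline miR-142-5p was at 0.80 (0.61 to 1.00) and miR-142-3p at 0.22 (-0.02 to 0.45). The hairpin lies in an intron of Mir142hg at chr 11 87756864-87756927. Both arms were well covered, with 1915.3 and 1479.3 mean nuclear reads with doxycycline. Arms of a hairpin did not rank alike in general. Over 68 pairs of a star strand and its partner, rho between their folds in that comparison was -0.11.

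Star strands, the arms of a hairpin that are usually discarded, made up 10 of the 15 entries at least 2-fold lower in the nuclear fraction, 3 of the 39 higher ones and 68 of the 378 tested. Among them were miR-27a* at -1.80, miR-30c-1* at -1.69, miR-26b* at -1.59 and miR-20a* at -1.22, named after their values were seen. Their nuclear reads were close to or below those without doxycycline: 31.7 against 70 for miR-27a*, 19 against 14.3 for miR-30c-1*, 2.67 against 6.67 for miR-26b* and 44 against 40.3 for miR-20a*. Of the others, miR-30e* (150.5 against 102.8), miR-30c-2* (14.7 against 11.7) and miR-186* (10.7 against 6) had more with doxycycline. miR-124* (34 against 109.7), miR-30b* (18.7 against 40.3) and miR-145* (5 against 5.33) had fewer. After subtraction miR-27a* and miR-26b* had too few reads for a fold, while miR-20a* went to -3.54 and miR-30c-1* to -2.81. The median over all 68 was -0.21, at percentile 0.01 of abundance-matched lists.

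miR-805 took most nuclear reads without doxycycline and had fewer with it, at 0.567 times in the nuclear and 0.842 times in the total fraction. Its removal left the nuclear gain in reads at 0.588 of the total gain, against 0.328 with it, so miR-805 alone did not make up the difference between these ratios. Sequencing depth enters both gains, so whether induction added less in the nuclear fraction cannot be told here. The entries with no RefSeq miRNA gene, miR-805 and miR-714 among them, had a median log2 ratio of reads (with over without doxycycline) of -0.10 over 13 nuclear entries and 2.16 over 9 total entries, at percentiles 0 and 0.07 of abundance-matched lists. Since miR-805 had prompted that test, it was left out, and the medians became 0.38 and 2.44, at percentiles 0.18 and 0.15. The set was mixed in nuclear mean reads with against without doxycycline. miR-1965 had 1033.3 against 88 and miR-1196 114.3 against 3, while miR-714 had 104 against 111.3 and miR-1940 11 against 43.7. As a hypothesis, some of the entries may count fragments of other RNAs that bind without the induced AGO2. Absence from the table of genes does not itself show what they are.

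Star strands gained fewer reads with doxycycline than other arms, at a median log2 ratio of 1.52 against 4.20 in the nuclear and 2.18 against 5.25 in the total fraction. Low abundance did not account for it, since both medians lay at percentile 0 of lists matched on the level with doxycycline. Reads split between near-identical copies did not either: over hairpins with whole counts in both arms, the star arm was lower by a median of -2.67 log2 units in the nuclear and -2.87 in the total fraction. The star arm had the lower ratio in 90.6% of 64 nuclear and 91.3% of 69 total hairpins. The star marks the less abundant strand, so comparisons within hairpins did not match the arms on abundance. In the nuclear fraction the star arm could also have the higher ratio. With more reads than its partner under doxycycline, it was higher by 1.49 log2 units for miR-154* (107.7 against 52 reads), 4.07 for miR-485* (91 against 18.3) and 0.17 for miR-140* (486 against 263.7). With fewer reads, it was higher by 2.40 for miR-299* (132 against 187), 0.28 for miR-411* (195 against 566.3) and 0.12 for miR-136* (380.7 against 1173). The smaller gain of star strands could reflect which strand the induced AGO2 kept, as a hypothesis. A background richer in star strands would give the same values, and these ratios cannot tell it from strand choice. Without doxycycline some star arms had more nuclear reads than their partners, such as miR-295* (461.7 against 356.7) and miR-30b* (40.3 against 6.33). Others had fewer, such as miR-294* (235.8 against 718.8) and miR-17* (12.7 against 20.4). Which explanation holds was not tested.

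Of the 39 miRNAs at least 2-fold higher in the nuclear fraction, 14 (35.9%) stayed so after the reads without doxycycline were subtracted and 19 (48.7%) after the scaled subtraction, which was added when the former was known. The other 25 lost their fold in the former because fewer than 10 mean reads were left in both fractions. Of the 39, 19 had at least as many nuclear reads without doxycycline, so background present without induction may account for many. All of the 10 with less than 0.1 times as many nuclear reads without doxycycline stayed (100%): miR-136, miR-136*, miR-15a, miR-193, miR-219, miR-297a*, miR-297c, miR-32, miR-466f-3p and miR-544, a group for which so low a background leaves little to subtract. Other settings kept fewer: 31 of the 39 stayed at least 2-fold higher without the filter and 28 without scaling. In both, miR-219, miR-297a*, miR-297c, miR-32 and miR-544 came within 2-fold. Arms of a hairpin did not always go together: miR-136 and miR-136* were both higher, while miR-193* was at -0.81 and miR-15a* at -0.51. Counts of miR-297c, miR-297a* and miR-466f-3p were not whole after multiplication by 3, so these entries are uncertain individually. miR-544 reached the minimum of 10 mean reads only in the nuclear fraction (10.3, against 6 in the total fraction). Hairpin GC, known for 32 of the 39, was at a median of 45.7% against 47.9% (percentile 10.7). The others, miR-805 and miR-714 among them, had no gene. All 39 (100%) had a lower counting bound above no change, which the minimum of 10 mean reads and the 2-fold size made likely. For those 10 a nuclear excess remains a hypothesis, since 1 library could dominate any mean and that was not tested.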
